A study of Mus musculus with 29 samples.

How the data were processed

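Polyadenylated RNA of CD4+ T cells from mouse spleen was sequenced with a strand-specific kit as single reads of 65 bases on a HiSeq 2500, per the labels' protocols. Per the submitters' processing notes, reads were aligned with STAR 2.7.3a to the mouse assembly GRCm39 and counted per gene with HTSeq 0.12.4. The deposited values are whole-number gene counts, without normalization, per the submitters' processing notes, which also name DESeq2 1.30.1 for their own testing. The strand setting of the counting and the annotation release are not given in the sources used here, so counts of overlapping and antisense genes are uncertain, as are those of near-identical genes between which reads may be split, such as Gimap3 and Gimap5 or Ifit3 and Ifit3b.

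Each of the 29 libraries holds counts for 55414 Ensembl gene identifiers, of which 52081 were matched to a symbol in a mouse gene annotation of another assembly, used for names alone, and 3333 were not. The unmatched identifiers took 0.332% to 1.05% of the gene counts. No coordinates are given for that reason. The summary entries of the counting that name no gene were left out of library sizes and tests: reads of low alignment quality made up 13.3% to 17.0% of the entries per library, reads in no gene 5.72% to 11.2% and ambiguous reads 1.01% to 1.13%. Gene counts per library ranged from 9754511 to 14315313. Mitochondrial transcripts took 0.63% to 1.69% and the 10 most abundant genes 4.18% to 5.57% of them.

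Libraries were grouped by time (24 or 72 h), sorted population (Tcon or Treg), TGF-beta and lactic acid, as labelled. Expression levels (CPM) are counts relative to library sizes scaled by TMM. Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with all 29 libraries in 1 fit, no covariates, and genes kept by filterByExpr (minimum count 10, minimum total 15), which left 14375 genes. Adjusted p-values are Benjamini-Hochberg values over those genes within a comparison, and genes below 0.05 are called. There were 20 comparisons: 5 of lactic acid, 4 of TGF-beta, 2 of Treg against Tcon, 4 of 72 h against 24 h, and 5 interactions. Fold changes use the prior count of 0.125 that edgeR adds. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic of its test. It is thus derived from the test and not fitted separately. Where a group had no counts, a fold is given as a lower bound against 3 counts over the group, and where it had few, as a ratio with an exact 95% interval. Such intervals and floors cover counting error only. A list of genes was tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, and its p-values were adjusted over the lists within a comparison. Of 32 lists written beforehand, 30 were meant for this test and 29 had enough measured genes.

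Design, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 5 protein-coding genes with the largest rise and the 5 with the largest fall (3 of each for time) among called genes with a mean of at least 5 CPM and no overlap between the libraries of both groups, which chance gives to 10% of genes with 3 libraries against 3. It adds up to 4 members of each list that passed or had at least 25% of its genes called, the 5 smallest p-values of an interaction, and a panel that includes Foxp3, Il2, Ikzf2 and Il2ra. Genes outside the rule are said to be chosen after their values were seen.

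Replicate numbers were checked for pairing. Within a time point, in every comparison with 3 shared numbers, same-numbered libraries deviated together from their group means across genes (correlations of 0.12 to 0.77). Between time points these correlations were -0.06 to 0.11 with 3 shared numbers and 0.15 with 2. Libraries of different numbers also deviated together at 72 h. Their highest correlation was 0.33 for TGF-beta with lactic acid and 0.24 for lactic acid in Tcon with TGF-beta. These exceed the lowest same-number values of 0.24 and 0.18, so pairing by each number is not clear there. The numbers were taken to pair libraries within a time point, and a fit with the replicate number within each time point as a block (6 blocks) was added after the data had been seen. Its value is given beside the results where it changes the call of a gene or list named there, or moves the number of genes called or of lists passing that is printed there by more than 1.5 times. Counts of members within a list come from the fit without it. On autosomal genes alone, 2 of the comparisons had a lowest correlation of 0.07 and 0.1, so part of the pairing is the shared sex of replicate 1. The other alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, the compared groups alone, the replicate number as a block over all libraries, each library left out in turn, an estimated correlation between genes and the self-contained test fry for the lists, and, added after the data had been seen, the 72 h replicate 1 libraries left out.

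The test was tried on simulated data with 200 genes changed by known folds, drawn from the means and sizes of these libraries (14205 to 14250 genes after the filter). In the 5 lactic acid comparisons it recovered 23.9% to 32.8% of genes changed 1.5-fold, 43.3% to 70.1% of those changed 2-fold and 75.8% to 89.4% of those changed 4-fold, with 3.9% to 7.3% of calls false. With the block within time points (14233 to 14266 genes) it recovered 59.7% to 70.1%, 67.2% to 83.6% and 84.8% to 92.4%, with 4.8% to 9.6% of calls false. Each fit was scored on data drawn from its own model, so these values do not compare the fits on the same data. The data for the fit without the block held no pairing of replicates, so its share of false calls was not tried with pairing present. Over all 11 comparisons of lactic acid, TGF-beta and Treg against Tcon, the lowest recovery of 1.5-fold changes was 19.4% without and 47.8% with the block. The share of false calls reached 10.5% and 11.8% for TGF-beta at 72 h without and with lactic acid, and 11.9% and 16% with the block, above the 5% aimed at.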

Results

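Gene expression was measured by sequencing polyadenylated RNA from CD4+ T cells isolated from the spleens of reporter mice. In these mice a red fluorescent protein (RFP) reports expression of Foxp3, the transcription factor that defines regulatory T cells. The cells were activated through CD3 and CD28 with interleukin 2 in medium with 0.5 mM glucose, with or without 3 ng/ml TGF-beta (the cytokine that induces Foxp3 in activated CD4+ T cells) and with or without 10 mM lactic acid. They were collected after 24 or 72 h. RFP-negative cells (called Tcon below) were sorted from all 4 media at both times, and RFP-positive cells (called Treg) from both TGF-beta media at 72 h. This gave 10 groups and 29 libraries, with 3 libraries per group except the 72 h Tcon group that received neither TGF-beta nor lactic acid, which had 2 (replicates 1 and 2). Replicate 1 came from male mice and replicates 2 and 3 from female mice, and the sex-linked transcripts matched the labelled sex in all 29 libraries. Between 9754511 and 14315313 reads per library were assigned to genes (median 12106958). Between 17810 and 20068 genes had at least 1 count. No source states that replicates 2 and 3 came from separate animals. The p-values rest on the spread within groups, estimated over all 29 libraries and not those compared alone, and this spread may in part be technical.

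The largest source of variation among the libraries lay between the times of collection: the first principal component, with 52.3% of the variance, separated 24 h from 72 h. The second, with 20.3%, separated cells with TGF-beta from cells without it within each time point. No source used here states whether both times belong to 1 experiment. Effects of time are therefore not separated from a difference between experiments, here or in the comparisons of the times below. The third component, with 7.8%, separated the 72 h replicate 1 libraries, with scores of 6.5 to 51.6, from the other 72 h libraries, with scores of -34.9 to -5.4. Replicates within a group correlated at 0.970 to 0.992 across genes on the log2 CPM scale. No pair of replicates was as close as counting noise alone would make it. Marker genes of other blood cells were summed per group: the mean sum of the B cell markers lay between 144.2 CPM and 360.7 CPM. That of the CD8 and natural killer markers lay between 22.3 CPM and 181.9 CPM, that of the myeloid markers between 25.6 CPM and 65.6 CPM, and that of the erythroid markers at 0.274 CPM or below. These sums moved with treatment. With TGF-beta at 24 h the B cell sum went from 258.3 ± 10.2 to 144.2 ± 3.46 CPM and the CD8 and natural killer sum from 83.1 ± 4.22 to 166.9 ± 21.8 CPM (SD, n = 3 each), and with lactic acid present from 245.2 to 158.7 CPM and from 82.8 to 181.9 CPM. The myeloid sum was higher in all 3 same-numbered pairs of both media (25.6 to 31 CPM and 28.3 to 34.1 CPM). Mitochondrially encoded transcripts were higher in all 3 pairs without lactic acid (6985.9 to 8968.0 CPM), while with it the pairs went both ways. At 72 h the myeloid sum went from 65.6 ± 25.7 CPM (SD, n = 2) to 33.1 ± 1.31 CPM (SD, n = 3) and the CD8 and natural killer sum from 26.6 to 95.1 CPM, and with lactic acid from 60.6 to 36.4 CPM and from 22.3 to 119.0 CPM. The chemokine gene Xcl1 made up much of the CD8 and natural killer sum and of these changes. With TGF-beta alone it went from 67 to 159.0 CPM at 24 h and from 2.41 to 59.4 CPM at 72 h. At 24 h Cd8a (0.987 to 0.397 CPM) and Cd8b1 (11.5 to 4.78 CPM) went down, so the sum does not measure the content of those cells.

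**Figure D1:**
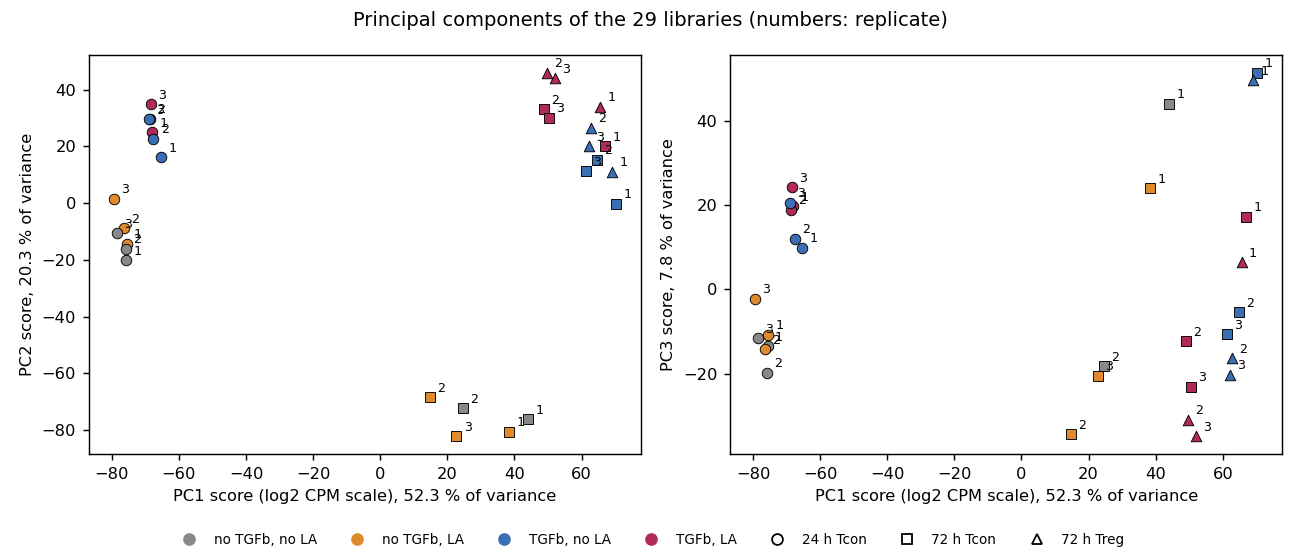
Scores of the 29 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM values, in arbitrary units; each point is 1 library and its number is the replicate. Component 1 (52.3% of the variance) separates 24 h from 72 h, component 2 (20.3%) TGF-beta from none within each time point, and component 3 (7.8%) the 72 h replicate 1 libraries from the other 72 h libraries.

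Foxp3 was measured first, because the cells had been sorted on its reporter. At 72 h with TGF-beta, the 6 Treg libraries held 153.2 to 572.5 CPM of Foxp3 and the 6 Tcon libraries 15.4 to 59.8 CPM. No library without TGF-beta exceeded 1.97 CPM. The ranges did not overlap, so the Foxp3 transcript followed both the sorting gate and the addition of TGF-beta. Foxp3 was therefore present in the RFP-negative gate as well, at 23.4 ± 10.8 CPM (SD, n = 3) with TGF-beta alone at 72 h and 48.2 ± 12.1 CPM (SD, n = 3) with TGF-beta and lactic acid.

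**Figure D2:**
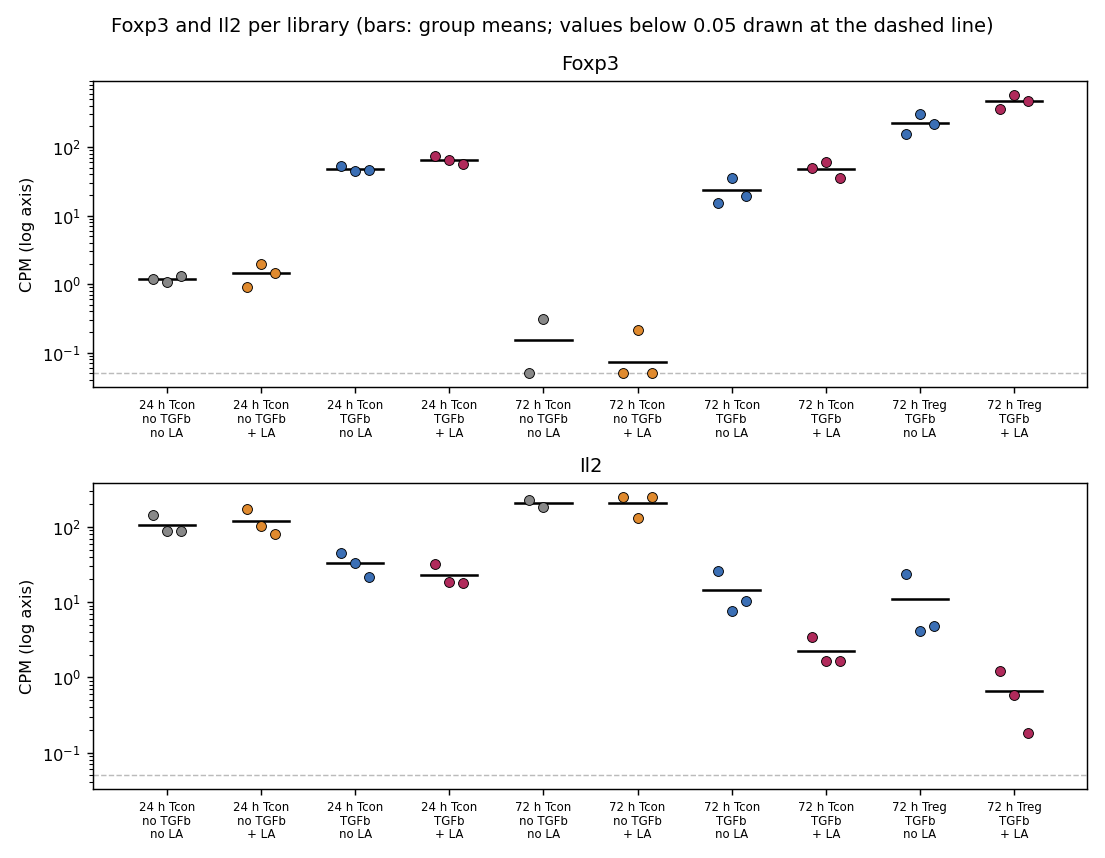
Foxp3 and Il2 levels in CPM (log axis) in each of the 29 libraries; points are libraries, bars are group means, and values below 0.05 CPM are drawn at the dashed line. Foxp3 was at most 1.97 CPM without TGF-beta and 153.2 to 572.5 CPM in the 6 Treg libraries.

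Treg sorted at 72 h from TGF-beta medium with and without lactic acid were compared. The acid was in the medium before sorting, so a change within Treg and a change in which cells became RFP-positive are not separated. Foxp3 itself rose with lactic acid, from 223.9 ± 75.5 to 467.5 ± 104.9 CPM (SD, n = 3 each; log2 fold change 1.06 ± 0.26, SE). Ikzf2, which encodes the Treg-associated transcription factor Helios, fell by 0.87 ± 0.20 on the log2 scale. The largest rises were in Ly6c1, a surface antigen of lymphocytes (3.61 ± 0.41), and in Gimap7 and Gimap4, GTPases with roles in lymphocyte survival (2.05 and 1.32). Txk, a Tec-family kinase of T cells (1.35), and Arsb, a lysosomal sulfatase (1.43), belonged to the same 5. The largest falls were in Il2, the T cell growth factor (-3.99 ± 0.80), Scin, an actin-severing protein (-2.55 ± 0.30), and Cd83, an activation-induced surface molecule (-2.41 ± 0.35). Next came Plagl1, a zinc finger transcription factor (-2.37), and Ccr6, a chemokine receptor of Th17 cells and Treg (-2.26). Il2 went from 10.9 to 0.666 CPM. In all, 504 of 14375 genes passed the test (edgeR, adjusted p below 0.05), 214 higher and 290 lower. Of these, 168 falls and 36 rises were at least 2-fold. The adjusted p was 0.024 for Foxp3, 0.0178 for Ikzf2 and 0.00633 for Il2. The fit that also paired replicates within a time point called 2833 genes, and that with the libraries of the compared groups alone 16. The count was 165 or 335 without replicate 1 or 3 of the group without lactic acid and 138 or 213 without replicate 2 or 3 of the group with it. The Foxp3 call was lost in each of these 4 fits, the Il2 call without the first replicate 1 and without replicate 2 of the lactic acid group, and the Ikzf2, Ccr6 and Arsb calls in 3, 3 and 4 of the 6 fits.

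Early activation genes fell together in Treg from lactic acid medium. Of the 23 measured genes of this list, 9 fell and none rose (18 fell when adjusted over the list alone). Among them were Csf2, which encodes the cytokine GM-CSF (-1.96 ± 0.29), Nr4a2, an immediate-early nuclear receptor (-0.90), and Irf4, a transcription factor induced by antigen receptor signals (-0.68). The list passed the gene set test at an adjusted p of 1.25e-16 and also with an estimated correlation (adjusted p = 0.0269). It was the only one of 29 lists that did so in this comparison, while 15 passed with the preset correlation. Genes of fatty acid oxidation went the other way: 5 of 16 rose and none fell (7 rose when adjusted over the list alone). They were led by Cpt1a, which imports long-chain fatty acids into mitochondria (0.79 ± 0.14), and included Acadl, Cpt2 and Acaa2, enzymes of the same pathway (0.41, 0.64 and 0.66). The preset-correlation p of that list was 1.68e-05, but the adjusted p = 0.172 with an estimated correlation. The amino acid response genes controlled by ATF4 had 2 of 30 lower, Stc2 and Atf3, with 2.78e-08 at the preset and adjusted p = 0.345 with an estimated correlation. Of the heat shock genes, 1 of 10 fell, the mitochondrial chaperonin Hspe1 (-0.54). Over the list alone, adjusted p-values called 8 lower (3.76e-05, and adjusted p = 0.276 with an estimated correlation). Of the genes named in this paragraph, Csf2, Nr4a2, Cpt1a and Stc2 kept their calls with any 1 of the 6 libraries left out, and Irf4, Acadl, Cpt2, Acaa2, Atf3 and Hspe1 lost them in 2 to 4 of those fits. Marker sums of other cells also moved in this comparison, in the same direction in all 3 same-numbered pairs: that of CD8 and natural killer cells went from 96.3 ± 7.13 to 73.5 ± 3.74 CPM, that of B cells from 288.3 ± 97.3 to 360.7 ± 53.1 CPM and that of myeloid cells from 34.6 ± 1.78 to 40.7 ± 4.13 CPM (SD, n = 3 each). Within the CD8 and natural killer sum, Xcl1 went from 72 to 40.6 CPM, while Cd8a (6.71 to 8.69 CPM) and Klrd1 (4.52 to 8.55 CPM) went up.

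In Tcon with TGF-beta at 72 h, many of the same genes moved with lactic acid. Ly6c1 (3.35 ± 0.37), Gimap7 (2.66 ± 0.32), and Upp1, a uridine phosphorylase (1.76), rose most. Abcb9, a lysosomal peptide transporter (1.66), and Gbp10, an interferon-inducible guanylate-binding protein (1.58), followed. Il2 (-2.67 ± 0.65), Cd83 (-2.66 ± 0.35), Sh3bp4, an endocytic adaptor (-2.60), Scin (-2.57) and Il9, a T helper cytokine (-2.55), fell most. Foxp3 had a log2 fold change of 1.04 ± 0.28 in these RFP-negative cells, close to that in Treg, but missed the threshold (edgeR, adjusted p = 0.0502; 2.09e-05 with replicates paired within a time point). Ikzf2, at -0.74 ± 0.20, likewise missed it (0.0617; 4.27e-05 paired). In total 311 genes passed (edgeR), 107 higher and 204 lower, 2211 with replicates paired and 38 with the compared groups alone. Leaving out replicate 1 or 3 of the group without lactic acid gave 116 or 200, and leaving out replicate 2 or 3 of the group with it gave 111 or 166. Ly6c1, Gimap7, Abcb9, Cd83 and Scin kept their calls in all 6 such fits. In contrast, Il2, Il9 and Gbp10 lost them in 3, Sh3bp4 in 2 and Upp1 in 5.

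Of the early activation genes, 5 of 23 fell in these Tcon and none rose, with 10 lower when adjusted over the list alone. Csf2 (-1.15), Rel, an NF-kappaB subunit (-0.73), and Nr4a2 (-0.76) were among them, each call being lost in 3 or 4 of the 6 fits with 1 library left out, as was that of Ifit3b below. The list reached 3.49e-09 with the preset correlation and adjusted p = 0.258 with an estimated correlation. Of the interferon response genes, Ifit3b alone of 24 rose (2.35 ± 0.53; 5 rose and 1 fell when adjusted over the list alone). The list median was 0.78, with 9.27e-06 at the preset and adjusted p = 0.521 with an estimated correlation. Ifit3b shares near-identical sequence with Ifit3, so reads may be split between them. None of the 29 lists passed here with an estimated correlation, and 8 passed with the preset value (15 with replicates paired). The summed mitochondrially encoded transcripts went from 8156.2 ± 397.7 to 13098.2 ± 3017.7 CPM in this comparison, the CD8 and natural killer marker sum from 95.1 ± 20.2 to 119.0 ± 19.4 CPM and the myeloid sum from 33.1 ± 1.31 to 36.4 ± 2.93 CPM (SD, n = 3 each), each higher in all 3 same-numbered pairs.

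The overlap between these 2 lactic acid comparisons, which share no library, was 191 genes in the same direction and none in opposite directions. Of these, 58 were higher in both, where independent lists would share 1.59. In turn 133 were lower in both, where 4.12 would be shared. The comparisons are not independent, however: same-numbered Tcon and Treg libraries of a medium deviated together from their group means (correlations of 0.49 to 0.77 without lactic acid and 0.32 to 0.65 with it), so part of the overlap can be shared noise. Across all 14375 genes, which are not independent replicates, the fold changes of the 2 comparisons correlated at a Pearson r of 0.60 and a Spearman rho of 0.55. The direct test of a different lactic acid effect in Treg and Tcon called 0 genes by edgeR (381 at an unadjusted p under 0.05; 0 by DESeq2). Chance alone would give such a p to a share of 0.05 of the genes, which is more than 381. The paired fit gave it to 1081 genes and called 0, so the 0 calls do not show equal effects. With replicates paired within a time point, the same overlap held 1417 genes.

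**Figure D3:**
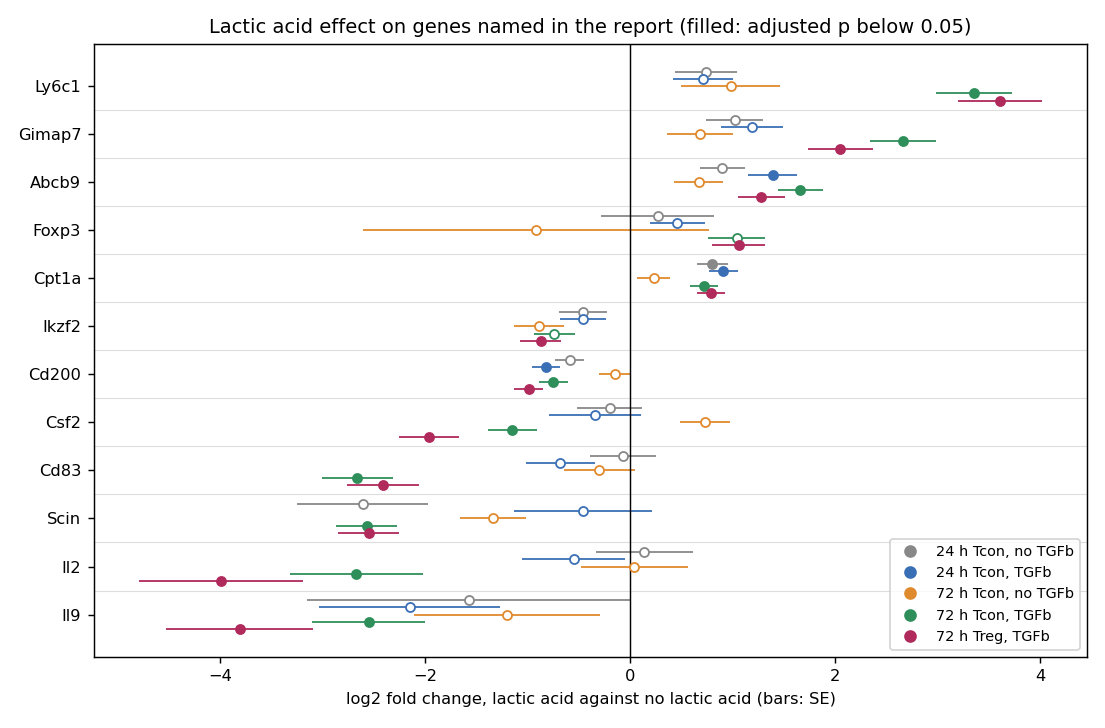
Log2 fold change of lactic acid against no lactic acid (points, with SE bars) for 12 genes in the 5 lactic acid comparisons; filled points passed the test (edgeR, adjusted p below 0.05). Ly6c1 and Gimap7 rose, and Il2, Cd83 and Scin fell, in both 72 h comparisons with TGF-beta.

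Without TGF-beta, few genes passed the test for lactic acid in Tcon at 72 h. Il6, an inflammatory cytokine, rose from 1.26 to 17.6 CPM (log2 fold change 3.79 ± 0.56), and Dus4l, a tRNA-modifying enzyme, rose by less (0.67 ± 0.13). Pdk2, a kinase that restrains pyruvate dehydrogenase (-2.60 ± 0.45), Col27a1, a collagen (-2.32), and Ccl1, a chemokine (-2.09), fell most. Lipg, a lipase (-1.39), Pdzk1ip1 (-1.38) and Slc25a42, a mitochondrial coenzyme A carrier (-0.77), also fell. Il2 did not pass the test, with 204.7 CPM without and 210.8 CPM with lactic acid (log2 fold change 0.04 ± 0.52, adjusted p = 0.986). The test called 10 genes (edgeR, 2 higher and 8 lower, adjusted p of 0.0314 for Il6), 1289 had an unadjusted p under 0.05 and DESeq2 called 59. The fit with replicates paired within a time point called 492, and edgeR on the compared groups alone 0. The control group had 2 libraries, 1 of them a replicate 1 library that stood apart on the third component. Without it no gene was called, and without the other 270 were. Each of these fits, like all others without a library of this group, leaves it 1 library and takes its spread from the other groups. Leaving out lactic acid replicate 1 gave 62 and replicate 2 or 3 gave 1 or none. The Il6 call was lost in 2 of these 5 fits and each other call named in 3. None of the 29 lists passed with an estimated correlation (9 did at the preset value).

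At 24 h, lactic acid raised Cpt1a without TGF-beta (0.80 ± 0.15) and with it (0.91 ± 0.14). Without TGF-beta, Ptprf, a receptor phosphatase (1.02 ± 0.19), Plin3, a lipid droplet coat protein (0.53), Mapk3, the kinase ERK1 (0.44), and Unc13d, a regulator of granule release (0.40), also rose. Pkp4, a junction plaque protein, fell by 0.52 ± 0.10. With TGF-beta, Sh3gl3, an endophilin (1.51 ± 0.27), Abcb9 (1.39), Tg (1.36) and Ppm1j, a protein phosphatase (0.86), rose. Vim, an intermediate filament protein (-0.98 ± 0.18), Scd2, a fatty acid desaturase (-0.93), Gtse1, a G2 regulator (-0.86), Rxra, the retinoid X receptor (-0.86), and Cd200, an immunoregulatory surface molecule (-0.82), fell. Foxp3 was 47.3 ± 4.38 CPM with TGF-beta alone and 64.9 ± 8.12 CPM with lactic acid added (SD, n = 3 each), a difference that did not pass (log2 fold change 0.46 ± 0.27, edgeR adjusted p = 0.73). Without TGF-beta the mitochondrially encoded transcripts went from 6985.9 ± 1228.0 to 9558.3 ± 2480.5 CPM with lactic acid, higher in all 3 same-numbered pairs, while with TGF-beta the pairs went both ways. Myeloid markers were higher in all 3 pairs of both media (25.6 to 28.3 CPM and 31.0 to 34.1 CPM), and B cell markers lower without TGF-beta (258.3 to 245.2 CPM) and higher with it (144.2 to 158.7 CPM). The CD8 and natural killer sum was higher in all 3 pairs with TGF-beta (166.9 to 181.9 CPM) and went both ways without it.

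Without TGF-beta 12 genes were called at 24 h (edgeR, 11 higher and 1 lower; 1027 at an unadjusted p under 0.05; 61 by DESeq2). With TGF-beta 33 were (23 higher and 10 lower; 1197 at an unadjusted p under 0.05; 93 by DESeq2). The adjusted p of Cpt1a was 0.0472 and 0.00423. Pairing replicates within the time point called 614 and 963, and the compared groups alone gave 146 and 90. Leaving out any 1 of the 6 libraries of the first comparison left 1 or 2 genes and ended the call of Cpt1a and of each other gene named there. In the second, 4, 7 or 13 genes were left without replicate 1, 2 or 3 of the group without lactic acid, and 12 or 4 without replicate 2 or 3 of the group with it. Each of the 10 genes named was lost in at least 2 of the 6 fits. The 2 media shared 6 of the 12 genes, all higher (333 in the same direction with replicates paired). The direct test of a different lactic acid effect with and without TGF-beta at 24 h called 0 genes (edgeR; 197 at an unadjusted p under 0.05; 0 by DESeq2). A share of 0.05 of the genes, which is more than 197, would have such a p by chance alone. The paired fit gave it to 612 genes and called 0, so equal effects are not shown. No list passed with an estimated correlation in either medium, against 13 and 12 with the preset value. Fatty acid oxidation genes with TGF-beta came closest to holding, with 1 of 16 higher (5 adjusted over the list alone), 5.56e-07 at the preset and adjusted p = 0.135 with an estimated correlation.

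At 72 h, 15 genes differed in their lactic acid response between Tcon with and without TGF-beta (edgeR, 4 with a higher and 11 with a lower response under TGF-beta; 1121 at an unadjusted p under 0.05; 54 by DESeq2; 652 with replicates paired; 1 with the compared groups alone). Gimap5, a lymphocyte survival GTPase, rose by 1.02 on the log2 scale with TGF-beta and had -0.13 without it, a difference of 1.15 ± 0.14 (adjusted p = 2.04e-04). Gimap3 had 1.51 and -0.18, a difference of 1.70 ± 0.24 (0.00201). Gimap3 and Gimap5 are close paralogs between which reads may be split. Lad1, a filament-anchoring protein, had -1.78 with TGF-beta and -0.04 without it (9.97e-04). Slc2a6, a lysosomal hexose transporter, had -1.66 and -0.15 (0.00349), and Tle1, a transcriptional co-repressor, -0.74 and 0.61 (0.00349). These 5 calls held without any 1 of the 11 libraries. The count of 15 became 6 or 30 without replicate 1 or 2 of the group without either addition, 7 without replicate 1 or 3 of the TGF-beta group, 7 without replicate 2 of the group with both, and 8 without replicate 3 of the lactic acid group. The response also differed between 24 h and 72 h in Tcon with TGF-beta for 4 genes, Lad1 (-1.28 ± 0.22), Marcksl1, an actin-regulating substrate of protein kinase C (-1.49 ± 0.26), Ly6c1 (2.64 ± 0.47) and Gimap5 (0.73 ± 0.13), each at an adjusted p of 0.0354 (edgeR; 821 at an unadjusted p under 0.05; 19 by DESeq2; 483 with replicates paired). That count was 3 without the 24 h TGF-beta replicate 1 and 0, 1 or 2 without any other of the 12 libraries. It was 0 with the compared groups alone (edgeR). The call of Ly6c1 was lost in 12 of the 12 fits with 1 library left out and those of Lad1, Marcksl1 and Gimap5 in 10. Without TGF-beta, 0 genes differed between the times (edgeR; 1313 at an unadjusted p under 0.05; 18 by DESeq2; 674 paired), and 40 did when replicate 2 of the 72 h control was left out.

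Of the genes chosen beforehand for their role in Treg or in lactate metabolism, 6 passed in none of the 5 lactic acid comparisons (edgeR). These were Il2ra, the high-affinity IL-2 receptor chain, Ctla4, an inhibitory receptor, Ifng, interferon gamma, Myc, a transcription factor of growth, Ldha, a lactate dehydrogenase subunit, and Slc16a1, a lactate transporter. Pairing replicates within a time point called some of them in Treg: Il2ra (0.39, adjusted p = 0.338 and 0.00723 paired), Ifng (-1.35, 0.128 and 0.00434), Slc16a1 (-0.30, 0.152 and 0.00105) and Myc (0.28, 0.665 and 0.0284). It also called Myc in Tcon with TGF-beta at 72 h (0.33, 0.656 and 0.0133). Ikzf2 was then lower without TGF-beta at 72 h (-0.89, 0.204 and 0.0092) and with it at 24 h (-0.46, 0.59 and 0.0378).

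**Figure D4:**
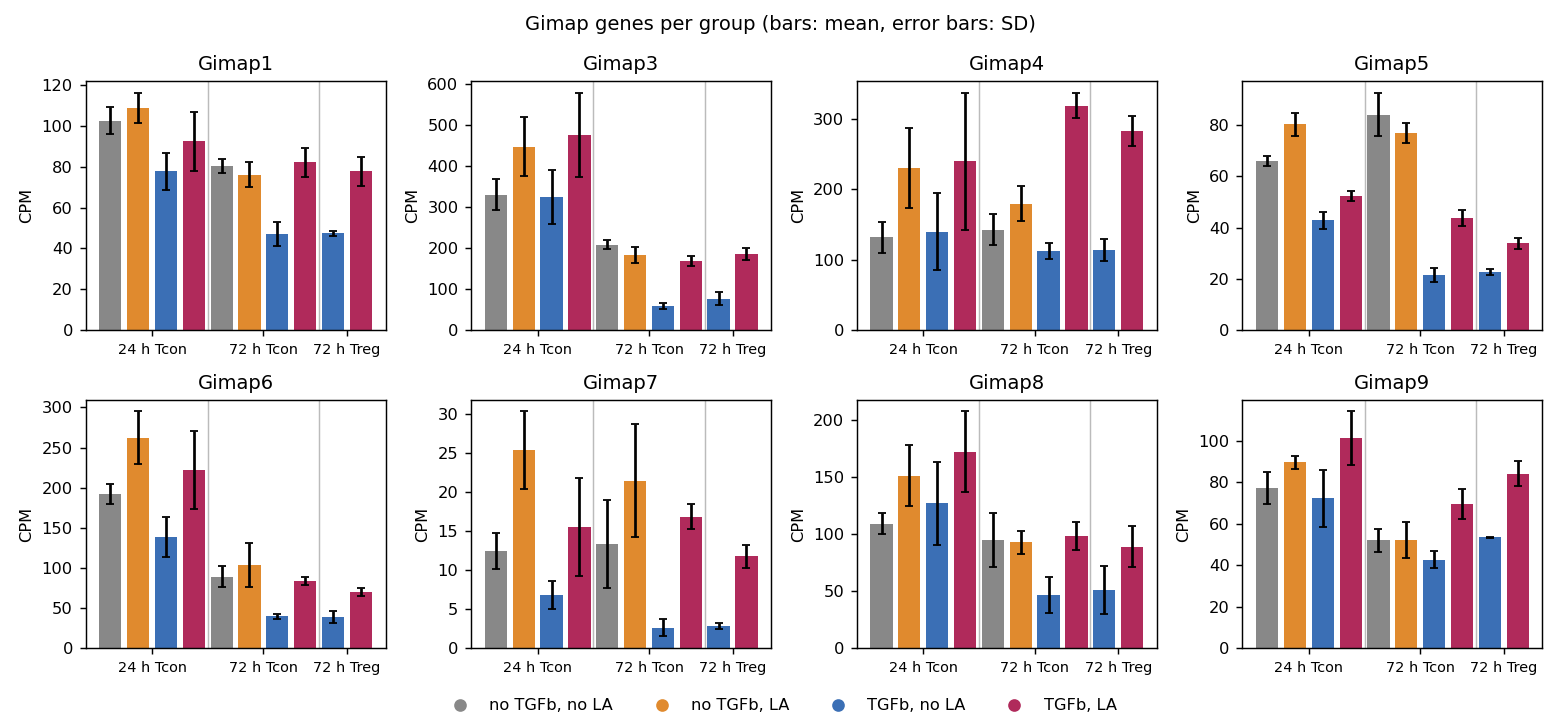
Level of 8 Gimap genes in CPM (group mean with SD bars) in the 10 groups. Gimap3 stood at 207.3 CPM without TGF-beta or lactic acid at 72 h, at 59 CPM with TGF-beta and at 168.7 CPM with both.

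TGF-beta at 24 h induced Foxp3 and a set of TGF-beta target genes in RFP-negative cells. Foxp3 rose from 1.2 ± 0.124 to 47.3 ± 4.38 CPM (SD, n = 3 each; log2 fold change 5.29 ± 0.39). Emp1, a membrane protein of epithelia (6.31 ± 0.33), and Aqp3, a water and glycerol channel (5.58), rose by as much or more. Fbxo2, a ubiquitin ligase subunit with no count in the control group, was at least 289.0-fold higher (against a floor of 3 counts over the group). Gzmb, a cytotoxic protease (-3.73 ± 0.40), and Eomes, a transcription factor of cytotoxic and memory cells (-3.16 ± 0.46), fell most. Serpinb9, an inhibitor of granzyme B (-2.60), Plk2, a kinase (-2.33), and Slco4a1, an organic anion transporter (-2.07), followed. Il2 fell by 1.68 ± 0.49, a call that was lost in 3 of the 6 fits with 1 library left out (adjusted p = 0.0261 with all). The test called 1625 genes (edgeR, 1144 higher and 481 lower; adjusted p of 1.12e-09 for Foxp3), 4562 with replicates paired and 3856 with the compared groups alone. It called 926, 1078 and 959 without control replicate 1, control replicate 2 or TGF-beta replicate 3.

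The Treg signature had 10 of 25 measured genes higher at 24 h and none lower (15 higher and 2 lower when adjusted over the list alone). It included Entpd1 and Nt5e, ectoenzymes that generate adenosine (3.49 and 4.34), and Capg, an actin-capping protein (2.92). The TGF-beta response list had 12 of 24 higher and 1 lower (15 and 2 adjusted over the list alone). Among these were Tgfbr1, the type I receptor (2.68), Ldlrad4 and Pmepa1, feedback inhibitors of the pathway (3.69 and 2.28), and Itgae, the integrin CD103 (4.73). Of the Th17 genes, 7 of 10 rose (8 adjusted over the list alone), among them Maf (4.13) and Rora (3.63), transcription factors of that lineage, and Ahr, the aryl hydrocarbon receptor (1.92). All 3 lists passed with an estimated correlation (adjusted p of 1.34e-06, 4.42e-05 and 0.00933), and no other of the 29 did, although 14 passed with the preset value. Itgae belongs to both the Treg signature and the TGF-beta response list, so the results of these lists are not fully separate, here or below. S phase genes had 5 of 26 lower and none higher (6 adjusted over the list alone; 5.82e-06 at the preset, adjusted p = 0.638 with an estimated correlation), with Tk1, thymidine kinase, at -1.22.

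With lactic acid present, TGF-beta moved the same leading genes at 24 h: Foxp3 (5.47 ± 0.38), Emp1 (6.80) and Aqp3 (5.68) rose, and Gzmb (-3.89), Eomes (-3.28), Plk2 (-2.58), Serpinb9 (-2.57) and Il2 (-2.37) fell. Here 1788 genes passed (edgeR, 1159 higher and 629 lower; adjusted p of 3.89e-10 for Foxp3), 4655 with replicates paired and 3305 with the compared groups alone. The count was 976, 1140 and 1088 without lactic acid replicate 1 or 2 or replicate 3 of the group with both. The Treg signature (13 of 25 higher, 1 lower; 15 and 1 adjusted over the list alone), the TGF-beta response list (11 of 24 higher, 1 lower; 12 and 1) and the Th17 list (6 of 10 higher; 7 higher and 1 lower) again passed with an estimated correlation, at adjusted p of 2.30e-06, 1.98e-04 and 0.0419. Early activation genes had 11 of 23 lower and none higher (16 lower and 1 higher over the list alone), including Egr3 (-1.08) and Cd40lg, the ligand for CD40 (-1.02), with 1.33e-06 at the preset and adjusted p = 0.241 with an estimated correlation.

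At 72 h without lactic acid, Foxp3 rose with TGF-beta against a control group with 4 counts (ratio 145.4, 95% counting interval 56.6 to 534.9), and so did Cdh1, the adhesion protein E-cadherin (148.9, 80.8 to 311.0). Rises were also seen in Aqp3 (91.6, 39.1 to 283.1) and Drc1, a component of motile cilia (log2 fold change 5.84 ± 0.67). Col5a3, a collagen, was lower by a ratio of 152.4 (73.6 to 380.3). Slc13a3, a dicarboxylate transporter (-5.26 ± 0.46), Ehd2, a membrane-trafficking ATPase (-5.11), Otx1, a homeobox factor (-5.06), and Dnah12, an axonemal dynein (-4.59), fell. Il2 dropped by 3.82 ± 0.56, from 204.7 to 14.6 CPM, and Ikzf2 rose (2.20 ± 0.25). The Treg signature had 12 of 25 higher and 3 lower (the same counts adjusted over the list alone), with Itgae (5.77), Nt5e (5.73) and Entpd1 (3.56) up and Tigit, an inhibitory receptor, down (-3.26). The TGF-beta response list had 14 of 24 higher and 2 lower (15 and 3 over the list alone). Both passed with an estimated correlation (adjusted p of 0.00183 and 0.0035). The test called 3517 genes (edgeR, 1834 higher and 1683 lower; adjusted p of 2.44e-08 for Foxp3), 6526 with replicates paired and 1058 with the compared groups alone.

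Several other groups moved with TGF-beta at 72 h, past the test with the preset correlation but not with an estimated one. Genes of the unfolded protein response had 14 of 19 lower and none higher (15 lower and 1 higher adjusted over the list alone). They included the chaperones and foldases Pdia6 (-1.09), Dnajb11 (-0.63), Manf (-0.93) and Creld2 (-1.21). The list had 9.85e-08 at the preset and adjusted p = 0.37 with an estimated correlation. Hypoxia genes had 9 of 19 higher and none lower (11 over the list alone). Among them were Egln3, an oxygen-sensing hydroxylase (1.16), and Bnip3, a mitophagy receptor (1.01). The list had 8.23e-05 and adjusted p = 0.63 with an estimated correlation. Markers of CD8 and natural killer cells had 4 of 6 higher and 1 lower (the same over the list alone): Cd8a, the CD8 alpha chain (from 0.359 to 9.52 CPM; 4.68 ± 0.97), Xcl1, the chemokine lymphotactin (4.63), and Klrd1, the receptor CD94 (2.53), rose. Prf1, perforin, fell (-3.08). Their preset p was 0.00463 and the adjusted p = 0.208 with an estimated correlation. The preset call was lost without control replicate 2 (0.122). Cd8b1, which encodes the other CD8 chain, did not pass (8.28 and 5.76 CPM; -0.52 ± 0.30, adjusted p = 0.223).

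With lactic acid present at 72 h, TGF-beta called 6471 genes (edgeR, 3237 higher and 3234 lower; 8621 with replicates paired). Foxp3 went from 0.0723 to 48.2 CPM, a ratio of 583.5 against 3 counts (95% counting interval 199.3 to 2832.6), with the adjusted p at 2.20e-11. Cdh1 (ratio 837.9, 286.4 to 4065.8) and Nt5e (log2 fold change 7.13 ± 0.43) also rose, and Gja5, a gap junction protein with no count without TGF-beta, was at least 160.7-fold higher. Otogl, an inner ear matrix protein, had no count with TGF-beta and was at least 119.8-fold lower. Il6 (150.7, 58.6 to 555.0) and Kcnk10, a potassium channel (135.8, 68.7 to 315.2), were lower by the ratios given. Il2 fell by 6.53 ± 0.65, from 210.8 to 2.24 CPM. The Treg signature (12 of 25 higher, 4 lower), the TGF-beta response list (12 of 24 higher, 2 lower; 13 and 2 over the list alone) and the CD8 and natural killer markers (4 of 6 higher, 1 lower) passed with an estimated correlation (adjusted p of 0.00103, 0.0222 and 0.0351). Genes of ribosome biogenesis had 23 of 27 lower and the ATF4 list 21 of 30 lower, with none higher in either. Both had the same counts over the list alone, preset p of 2.34e-05 and 5.21e-06, and adjusted p = 0.623 and 0.554 with an estimated correlation.

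Few genes passed the test between sorted Treg and Tcon from the same TGF-beta medium at 72 h. The B cell marker sum was higher in Treg in all 3 same-numbered pairs (243.3 ± 79.1 CPM in Tcon and 288.3 ± 97.3 CPM in Treg, SD, n = 3 each). Foxp3 was 3.26 ± 0.29 higher on the log2 scale in Treg, by whose reporter the cells had been sorted. Itgb8, an integrin that activates latent TGF-beta (2.03 ± 0.34), and Tnfrsf8, the activation receptor CD30 (1.65 ± 0.26), were also higher, followed by Car5b, a mitochondrial carbonic anhydrase (1.44), Myb, a transcription factor (0.87), and Itga6, an integrin (0.81). Il13, a Th2 cytokine (-3.77 ± 0.60), Ifit1, an interferon-induced protein (-2.23), Mpzl2, an adhesion molecule (-2.06), Sema6d, a semaphorin (-1.98), and Ccn4, a matricellular protein (-1.67), were lower. The test called 31 genes (edgeR, 9 higher and 22 lower; 80 by DESeq2; 809 at an unadjusted p under 0.05; 422 with replicates paired; 0 with the compared groups alone), with adjusted p of 1.11e-06 for Foxp3 and 0.0067 for Il13 and Tnfrsf8. The count was 50, 6 or 14 without Treg replicate 1, 2 or 3 and 2 without Tcon replicate 3. Foxp3 was the only gene named here that passed in all 6 such fits. The Treg signature, with 2 of 25 higher (6 higher and 1 lower over the list alone), and the Th1 list, with none of 17 past the test (2 lower over the list alone), passed with an estimated correlation, at adjusted p of 2.38e-05 and 0.0433.

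With lactic acid the sorted populations differed in 366 genes, 183 in each direction (edgeR; 1832 with replicates paired; 193 with the compared groups alone). Marker sums differed as well, in the same direction in all 3 same-numbered pairs: from Tcon to Treg, B cell markers went from 271.5 ± 33.1 to 360.7 ± 53.1 CPM, CD8 and natural killer markers from 119.0 ± 19.4 to 73.5 ± 3.74 CPM, myeloid markers from 36.4 to 40.7 CPM and mitochondrially encoded transcripts from 13098.2 ± 3017.7 to 8487.5 ± 918.4 CPM (SD, n = 3 each). Foxp3 was 3.28 ± 0.29 higher in Treg (adjusted p = 7.41e-07). Next were Efna5, an ephrin (2.49), Sgk1, a salt-responsive kinase (2.30), Pld4, an endolysosomal exonuclease (2.15), and Car5b (1.97). Il2ra was higher by 0.76 ± 0.20 (0.0447). Il13 (-5.48 ± 0.76), Ifit1bl1 (-3.30), Sema6d (-2.94), Ifit1 (-2.83) and Klrk1, the receptor NKG2D (-2.42), were lower. So was Il10, an anti-inflammatory cytokine, at -2.37 ± 0.39 (0.00122). Of the Th1 genes 5 of 17 were lower and none higher (8 lower over the list alone). Among them were Il12rb2, an IL-12 receptor chain (-1.35 ± 0.17), Fasl, a death ligand (-1.28), Tbx21, the Th1 transcription factor T-bet (-0.65), and Ccl3, a chemokine (-1.29). Of the Th17 genes 3 of 10 were lower (6 over the list alone), including Ahr (-0.87) and Ccl20 (-1.77). Of the lactate and proton handling genes 2 of 19 were lower (4 over the list alone), Gpr65, a proton-sensing receptor (-0.48), and Car2, a cytosolic carbonic anhydrase (-1.01). These lists and the Treg signature (6 of 25 higher, 1 lower, the same over the list alone) passed with an estimated correlation, at adjusted p of 6.30e-04, 0.0246, 0.0246 and 0.00399. The count of 366 became 176, 189 or 219 without Tcon replicate 1, 2 or 3 and 100 or 171 without Treg replicate 2 or 3. The calls of Il2ra, Efna5, Pld4, Gpr65 and Car2 were lost in 5 or 6 of the 6 such fits, and those of Sgk1, Ccl20, Ifit1bl1, Ccl3 and Tbx21 in 1 to 4. A higher count than without lactic acid does not show a wider difference between the populations. The direct test is that of a different lactic acid effect in Treg and Tcon. It called 0 genes (edgeR; 381 at an unadjusted p under 0.05; 0 with replicates paired), which does not show equal differences either.

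Between 24 h and 72 h, 6538 to 7588 genes differed in Tcon of the 4 media (edgeR), with time not separated from a possible difference between experiments. The CD8 and natural killer marker sum went down in each medium, from 83.1 to 26.6 CPM without additions, 82.8 to 22.3 CPM with lactic acid, 166.9 to 95.1 CPM with TGF-beta and 181.9 to 119.0 CPM with both. Within it, Xcl1 alone went from 67 to 2.41 CPM without additions and from 159.0 to 59.4 CPM with TGF-beta. The myeloid sum went up from 25.6 to 65.6 CPM without additions and from 28.3 to 60.6 CPM with lactic acid, and the B cell sum from 144.2 to 243.3 CPM with TGF-beta and from 158.7 to 271.5 CPM with both. Without TGF-beta and lactic acid, Vldlr, a lipoprotein receptor with no count at 24 h, was at least 687.4-fold higher at 72 h. Nos2, inducible nitric oxide synthase, rose from 1 count to a ratio of 1309.5 (95% counting interval 234.4 to 51781.8). Xcl1 (-4.80 ± 0.29), Klf2, a transcription factor of resting T cells (-4.24 ± 0.71), and Ifi209, an interferon-inducible protein (-4.11 ± 0.78), fell. Glycolysis genes had 18 of 19 higher, hypoxia genes 17 of 19 and G2 and M phase genes 22 of 22, with none lower (19, 17 and 22 over the list alone). All 3 lists passed with an estimated correlation (adjusted p of 0.0161, 0.0266 and 0.0473). Ribosome biogenesis genes had 24 of 27 lower and none higher (26 over the list alone; 4.37e-07 at the preset, adjusted p = 0.53 with an estimated correlation). The count of 6538 became 3973 without the 72 h replicate 1 library.

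In the other media the same 3 lists rose with time. With lactic acid alone 6701 genes passed (edgeR). Nos2 and Nupr1, a stress-induced chromatin protein, had no count at 24 h and were at least 376.8-fold and 290.3-fold higher. Xcl1 fell by 6.89 ± 0.30. With TGF-beta alone 7588 passed. Vldlr was at least 925.5-fold and Mt2, a metallothionein, at least 527.9-fold higher. With both, 6811 passed. Smtnl2 was at least 419.7-fold and Emilin2, a matrix glycoprotein, at least 156.6-fold higher. Pou2af1, a transcriptional coactivator, fell by 4.07 ± 0.55. Glycolysis genes had 17, 18 and 18 of 19 higher in these media, with 1 lower in the last (the same over the list alone), at adjusted p of 0.0439, 0.00395 and 0.00702 with an estimated correlation. Hypoxia genes had 17, 18 and 18 of 19 higher (17, 18 and 19 over the list alone; 0.0452, 0.0102 and 0.0112), and G2 and M phase genes 22 of 22 in each (0.0439, 0.0209 and 0.0106).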

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

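The tests of explanations in this part, and the counts over other splits of the samples, were chosen after the results had been seen. The interaction tests themselves were planned. What drew attention was a difference between groups in the effect of lactic acid. In Tcon at 72 h, 15 genes responded differently with and without TGF-beta (edgeR), led by Gimap5 (adjusted p = 2.04e-04), Lad1 (9.97e-04), Gimap3 (0.00201), Slc2a6 (0.00349) and Tle1 (0.00349). Between 24 h and 72 h in Tcon with TGF-beta, 4 genes did so, Lad1, Marcksl1, Ly6c1 and Gimap5, each at an adjusted p of 0.0354, calls that were lost in 10 to 12 of the 12 fits with 1 library left out. Between Treg and Tcon, the Th1 effector list differed in its lactic acid response with an estimated correlation (camera, adjusted p = 0.0357; 6.76e-05 at the preset correlation; median -0.41), although none of its 17 genes was called and fry gave 0.294. The CD8 and natural killer markers moved with it: their sum went from 96.3 to 73.5 CPM with lactic acid in Treg and from 95.1 to 119.0 CPM in Tcon, and their list passed this interaction at the preset correlation (0.00393) but not with an estimated one (0.24). Among them Xcl1 went from 72 to 40.6 CPM in Treg and from 59.4 to 56.6 CPM in Tcon, while Klrd1 rose in both (4.52 to 8.55 CPM and 4.8 to 11.8 CPM).

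The 15 genes with a TGF-beta-dependent response at 72 h had a median difference of log2 fold changes of 1.33 where it was positive and -1.35 where negative. The groups do not hold the same replicate numbers, since the control has no replicate 3. Without the 72 h replicate 3 libraries all 15 kept their direction, and 1 of them still passed with fewer libraries. Their fold changes were 0.94 of their size (median ratio). The 15 were called from data that hold these libraries, which favours genes whose libraries agree. An unchanged direction and a ratio near 1 were therefore likely in advance. The ratio describes the size of these differences without the replicate 3 libraries, and does not weigh the imbalance. The same holds for the 72 h replicate 1 libraries, which stand apart: without them all 15 kept their direction and the median ratio was 0.91. The control group is then 1 library, so calls made there are not weighed. A larger share of resting cells under lactic acid with TGF-beta would raise genes of naive T cells and lower those of early activation. The naive list had a median of 0.20 (SE 0.15, 19 genes) and the early activation list -0.33 (SE 0.20, 23 genes), against 1.33 and -1.35 for the 15. The 15 were picked for passing the test, so lists that were not picked would fall short of them under most causes. The gap therefore does not decide for or against resting cells. The early activation list did move in the direction that resting cells would give: it passed at the preset correlation (adjusted p = 2.58e-05, and without any 1 library), though not with an estimated one (0.266). A part played by resting cells therefore stays open, and so does a response to lactic acid that depends on TGF-beta, as a hypothesis that may hold for these genes. Reads shared between Gimap3 and Gimap5 remain possible for that pair.

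Cd8a rose with TGF-beta at 72 h in cells sorted as CD4+ T cells, by 4.68 ± 0.97 on the log2 scale without lactic acid and 5.40 ± 0.86 with it. Reads from CD8 T cells would bring Cd8b1 along, which equal gains in CPM would raise by 1.07 and 1.25. The highest value that Cd8b1 allows, its log2 fold change plus 2 SE, was 0.51. Natural killer cells would bring Ncr1 and Klrb1c, whose highest group mean was 0.203 CPM. Natural killer cells are thus argued against by the data. The Cd8b1 bound counts against CD8 T cells only if TGF-beta left Cd8b1 of the other cells unchanged. At 24 h Cd8b1 went from 11.5 to 4.78 CPM with TGF-beta, so a gain could be masked, and CD8 T cells stay open. Cd8a also varied between replicates (9.52 ± 6.7 CPM with TGF-beta alone at 72 h, SD, n = 3). Expression of Cd8a by TGF-beta-treated CD4+ T cells may account for the rise, as a hypothesis from the same data. Other cell sources were not tested. Cd8a in CD4+ T cells by any other route was not tested.

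Other splits of the same samples were counted for the comparisons with at least 3 libraries per group. For the 12 comparisons of 3 libraries with 3, 1 of the 10 splits, the real one, called as many genes, and 10 splits are too few to give a share under 0.05. The highest count of another split was 0, except 8 against the real 33 for lactic acid with TGF-beta at 24 h, 4 against 31 and 12 against 366 for Treg against Tcon without and with lactic acid, and 1 against 6701 for time with lactic acid alone. The splits that parted as many same-numbered pairs as the real one called 0. For interactions 40 of 200 splits were drawn. For lactic acid by TGF-beta at 24 h and lactic acid by population at 72 h, the real count was 0 (edgeR; 197 and 381 at an unadjusted p under 0.05; 0 by DESeq2), so 40 of 40 splits called as many whatever the samples hold, which decides nothing. The highest other counts were 361 and 3076, in splits that mix the lactic acid groups and so can carry part of the effect of lactic acid itself. What structure of the samples lies behind them was not tested. For lactic acid by time with TGF-beta, 5 of 40 splits called at least the real 4, with 17 as the highest. Apart from the real one, these splits kept the 3 libraries of a group together at 1 of the times. They can therefore carry the effect of lactic acid itself and do not measure chance, which is not excluded for those 4 genes.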

How the results depend on the processing

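The values with replicates paired within a time point, and those without the 72 h replicate 1 libraries, were chosen after seeing the data. The other alternatives were planned. The counts for TGF-beta with lactic acid at 72 h, for lactic acid by TGF-beta at 24 h and for lactic acid by population stayed within 1.5 times of their values under every alternative run for them, and so did the time comparisons with the exception given below. The block within time points was not run for the time comparisons, whose groups share no block. No named gene reversed direction in a comparison where it was called with or without the alternative. Of the 235 list results past the test none reversed under the other alternatives tried for lists, but 8 did in 1 fit each with a library left out, and passed in none of those (adjusted p of 0.415 to 0.965). These were the G2 and M phase list for lactic acid at 24 h without TGF-beta (without lactic acid replicate 3) and 7 at 72 h. Without control replicate 1 they were ribosome biogenesis for lactic acid without TGF-beta, and ribosome biogenesis and oxidative phosphorylation for lactic acid by TGF-beta. Without Treg replicate 1 of the TGF-beta medium they were the citrate cycle and oxidative phosphorylation for lactic acid in Treg and the citrate cycle for lactic acid by population. Without Tcon replicate 1 of the medium with both it was hypoxia for Treg against Tcon. Unless a reason is given, the cause was not tested.

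For lactic acid at 24 h without TGF-beta, 12 genes became 1 with RLE scaling, 37 without the low-count filter, 55 with the replicate block, 614 with the replicate block within time points, 146 with the compared groups alone and 61 with DESeq2. With TGF-beta, 33 became 21 with RLE, 99 and 963 with the blocks, 90 with the compared groups alone and 93 with DESeq2. At 72 h without TGF-beta, 10 became 65 without the filter, 42 and 492 with the blocks, 2 without the 72 h replicate 1 libraries, 0 with the compared groups alone and 59 with DESeq2. For Tcon with TGF-beta, 311 became 543 without the filter, 835 and 2211 with the blocks, 816 without the 72 h replicate 1 libraries, 38 with the compared groups alone and 503 with DESeq2, and for Treg 504 became 1187, 2833, 1132 and 16 with the blocks, without those libraries and with the compared groups alone.

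For TGF-beta at 24 h, 1625 became 4562 with the replicate block within time points and 3856 with the compared groups alone, and with lactic acid 1788 became 4655 and 3305. At 72 h 3517 became 6526 and 1058. For Treg against Tcon, 31 became 95 without the filter, 98 and 422 with the blocks, 131 without the 72 h replicate 1 libraries, 0 with the compared groups alone and 80 with DESeq2, and with lactic acid 366 became 678, 1832, 875 and 193 with the blocks, without those libraries and with the compared groups alone. For lactic acid by TGF-beta at 72 h, 15 became 47, 65, 652, 77, 1 and 54 in the order used for 31. By time with TGF-beta, 4 became 16, 13, 483, 68, 0 and 19. By time without it, 0 became 22 without the filter, 1 and 674 with the blocks and 18 with DESeq2. The overlap of 191 genes became 535 and 1417 with the blocks. Of 580 list tests 235 passed, 40 with an estimated correlation and 149 by fry. The fits with the compared groups alone have fewer libraries from which to estimate the spread. That does not explain the higher counts these fits gave for lactic acid and TGF-beta at 24 h. Such fits also leave out the 72 h libraries. Replicate pairs at 72 h that include replicate 1 correlated at 0.9704 to 0.9838, and pairs at 24 h at 0.9859 to 0.9923. The fit of all libraries thus brings a larger spread to the 24 h tests, whose counts rose without the 72 h replicate 1 libraries, as given next. How much of the higher counts this accounts for was not tested.

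The 72 h replicate 1 libraries are in none of the 24 h comparisons but share in the estimate of spread. Without them the 24 h counts also moved: 12 and 33 for lactic acid became 156 and 378, and 1625 and 1788 for TGF-beta became 4067 and 4266.

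With 1 library left out, the lactic acid counts ranged from 1 to 2 and 4 to 24 at 24 h without and with TGF-beta, and at 72 h from 0 to 270 in Tcon without it, 111 to 318 in Tcon with it and 138 to 630 in Treg. The TGF-beta counts ranged from 926 to 1543 and 976 to 1756 at 24 h without and with lactic acid, and from 2362 to 3246 and 5090 to 6419 at 72 h. Treg against Tcon gave 2 to 50 and 100 to 369. The time counts ranged from 3973 (without the 72 h control replicate 1, the lone library of its group then being assumed to vary like the others) to 6760, 5752 to 6368, 6567 to 7223 and 5761 to 6346. The interactions gave 6 to 30 for lactic acid by TGF-beta at 72 h, 0 to 3 and 0 to 40 by time with and without TGF-beta, and 0 for the rest, and the list tests 217 to 256. Of the results of named genes, the compared groups alone took 103 below the threshold and brought 7 past it. These numbers were 17 and 14 without the 72 h replicate 1 libraries, 15 and 11 without the filter, 9 and 1 with RLE, 3 and 5 with DESeq2, 0 and 9 with the replicate block and 0 and 23 with the block within time points. Depth limits genes with few counts, whose folds are given as bounds or ratios.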

Other observations

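The tests in this part were chosen after the results had been seen, as were the genes. Of the 8 Gimap genes measured, which encode GTPases of lymphocyte survival, all 8 rose with lactic acid in Tcon with TGF-beta at 72 h (log2 fold changes of 0.70 to 2.66) and 7 in Treg (0.57 to 2.05), the exception being Gimap8 (0.80, edgeR adjusted p = 0.0887; 2.25e-05 with replicates paired). TGF-beta alone lowered 6 of the 8 at 72 h (-2.33 to -0.78) and 7 with replicates paired, Gimap9 being added (-0.28, adjusted p = 0.177; 0.0121 paired). Gimap3 went from 207.3 ± 11.1 CPM (SD, n = 2) to 59 ± 7.66 CPM (SD, n = 3), and to 168.7 ± 12.3 CPM (SD, n = 3) with lactic acid added. None was called with lactic acid at 72 h without TGF-beta (edgeR; -0.18 to 0.68; 0 by DESeq2 and 0 with replicates paired). At 24 h all 8 lay above 0 with lactic acid in both media, and edgeR called 0 (0.08 to 1.02 without TGF-beta and 0.25 to 1.19 with it). DESeq2 called 0 and 3 of them and the fit with replicates paired 6 and 7, so a rise without TGF-beta is not excluded. These directions and the counts at 72 h were the same with RLE scaling. Ly6a, which encodes the surface antigen Sca-1, rose with lactic acid at 72 h in Tcon with TGF-beta, from 293.1 ± 79.9 to 720.4 ± 159.2 CPM (SD, n = 3 each; edgeR, adjusted p = 1.18e-04). It also rose in Treg, from 201.6 to 471.8 CPM (1.23 ± 0.17, 2.98e-04). Of the 5 Ly6 genes measured, all 5 lay above 0 in both comparisons, and 2 were called in each, Ly6a and Ly6c1. Ly6c2, Ly6e and Ly6k were not called (edgeR). With replicates paired, 4 of the 5 were called in each.

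Beside Cd8a, other genes known from CD8 T cells were picked by hand, without a test of them as a group, and they went both ways with TGF-beta in Tcon. At 72 h Runx3, a transcription factor of CD8 T cells, went from 145.9 to 271.2 CPM, Itgae from 1.03 to 55.9 CPM and Xcl1 from 2.41 to 59.4 CPM, while Cd4 stood at 642.3 and 574.3 CPM. Prf1 fell by 3.08 on the log2 scale and Cd8b1 did not pass (-0.52 ± 0.30), and at 24 h Gzmb (-3.73) and Eomes (-3.16) fell.

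A first hypothesis was that lactic acid moves genes of Treg in the same direction as TGF-beta moves those of Tcon at 72 h, in comparisons that share no library, although same-numbered libraries of a time point deviate together. Of 258 genes called in both, 194 (75.2%) went the same way, 84 higher and 110 lower in both, where 49.9% would if the directions were independent. Across all genes, which are not independent replicates, the fold changes correlated weakly (Pearson 0.18, Spearman 0.19). Most of the genes called went in the direction the hypothesis needs, while 24.8% went the other way. Treg without lactic acid and the 72 h control enter the comparisons with the same sign, and Treg and Tcon with TGF-beta alone with opposite signs. Shared noise can thus act either way, and the test does not set the hypothesis apart from it.

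The second hypothesis was that lactic acid holds back changes that come with time in culture. Of 326 genes called both for lactic acid in Treg and for time in Tcon without additions, 73.0% went opposite ways (170 lower with lactic acid and higher with time, 68 the reverse) and 88 the same way, where 45.4% would go the same way if the directions were independent. Across all genes the fold changes correlated at a Pearson r of -0.38 and a Spearman rho of -0.23. The directions are those the hypothesis needs, but the test does not set it apart from noise. Same-numbered 72 h libraries deviate together, and Treg without lactic acid and the 72 h control enter the comparisons with opposite signs, so shared noise gives opposite directions as well. The bound set against the hypothesis, 50% opposite, also lies below the share that independent directions give. The time comparison was made in Tcon and not in Treg, for which 24 h libraries are not among those used here. It also does not separate time from a possible difference between experiments.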
